A study of Mus musculus with 6 samples.

How the data were processed

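The series compares mouse embryonic fibroblasts starved for 6 h (3 arrays) with fibroblasts in normal medium (3 arrays). Per the labels, total RNA was extracted and biotin-labelled cRNA was hybridised to short-oligonucleotide expression arrays with 1 sample per array. The authors deposited a table of 1 value per probe set and array on the log2 scale. Per the submitters' processing notes the values were made with affy and RMA, whose versions are not given in the sources used here. RMA corrects the background, normalizes arrays by quantiles and summarises the probes of a probe set, which fixes the overall signal distribution of each array. A change in the total amount of messenger RNA per cell is therefore removed from the values before any test, and folds of dim genes are compressed. The deposited arrays had nearly the same distribution, with a largest distance of 0.0817 on the log2 scale between a sorted array and the mean sorted array. Array medians lay between 6.733 and 6.815. Array signals hold no read depth, so the number of arrays limits the precision.

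Probe sets were named through the platform annotation table provided with the values, and symbols were checked by gene identifier against a table of RefSeq genes. Of 22690 probe sets 64 were array controls, 20380 had 1 gene, 691 several and 1555 none listed. Gene identifiers of 20351 probe sets were found in the RefSeq table and 0 symbols needed updating. Probe sets with several genes or none listed and the controls were left out of the tests. A gene with several probe sets took the brightest over all 6 arrays, which left 12393 genes. Of these, 4956 had several probe sets, and for 116 of them a called probe set went opposite to the called one used. No filter on dim genes was applied, and no coordinates are given. Of the 945 members of the gene lists 829 were measured, and the others were not analysed here. Tfe3 and Gapdh, which the rule for named genes includes, had no probe set with 1 gene among those used, and further genes of that rule were not analysed here.

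Groups were taken from the sample titles. All 6 arrays entered a fit with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all 12393 genes and a threshold of 0.05 on the adjusted p. The 36 gene lists, written from textbook knowledge and each named in the report, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists, and beside it with an estimated correlation, with camera on ranks and with fry. Single values were compared with exact two-sided permutation tests, whose smallest p for 3 arrays against 3 is 0.1. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The groups, tests, gene lists and most alternatives were fixed before the data were examined.

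Genes named in the text follow a rule. It takes the 10 largest rises and the 10 largest falls past the threshold whose groups do not overlap, leaving out unnamed gene models. From each called list it takes up to 2 risen and 2 fallen members with the smallest adjusted p. It adds genes fixed beforehand whatever their values, among them Tfeb, Mcoln1, Sqstm1, Map1lc3b, Ulk1, Asns, Trib3, Ddit3, Ddit4, Fos, Myc, Ccnd1, Txnip and Actb. Members of a list outside this rule were named after their values were seen, either because 5 or fewer members moved that way or because they were the highest or lowest of their list.

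The alternatives were the mean of a gene's probe sets, leaving out probe sets that can bind several transcripts, leaving out the dimmest 40% of genes, a further quantile normalization, centring each array on its median, eBayes with trend and robust settings, array weights, a fit with the replicate number as a block, leaving out each array in turn, testing each probe set on its own, an adjusted p below 0.01, a log2 fold change of at least 1, and limma's treat against a fold change of 1.2. Centring on the poly-A spike-ins and on the hybridization spike-ins was added after the data were seen. The steps were tested on simulated data for the comparison of starved with control arrays, with 12393 genes and 200 changed genes in each of 10 simulations. The fit recovered 67.8% of genes changed by 0.5 on the log2 scale, 98.1% of those changed by 1 and 100% of those changed by 2, and 4.41% of its calls were unchanged genes. A list shifted by 0.5 was called in 10 of 10 simulations by camera with either correlation and by fry. Camera with the preset correlation called 0 unshifted lists. Simulated genes were drawn independently of each other, and far fewer of them changed than the 44.1% called in the real arrays. The simulations therefore do not show how often lists of correlated genes are called falsely or missed in the real arrays.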

Results

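Gene expression was measured with short-oligonucleotide arrays in mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos and described in the labels as wild type. RNA from cells starved for 6 h was hybridised to 3 arrays, and RNA from control cells kept in normal growth medium to another 3. The labels do not say which nutrients or serum components were withdrawn. The comparison asks which transcripts differ between starved and fed fibroblasts. Sample titles call the arrays of a group biological replicates without stating whether these came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera with its preset correlation rests on the spread between genes, so its p-values can overstate what 3 arrays against 3 show. Levels below are log2 array signals as mean ± SD (n = 3 arrays per group), and differences are starved minus control on the log2 scale, with their SE. The median SD of a gene was 0.075 within control and 0.102 within starved arrays.

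Starved fibroblasts had higher levels of interferon-stimulated genes and lower levels of genes for cholesterol synthesis, and in both groups every measured member of the list passed the test (for the interferon list, adjusted p = 0.0689 with an estimated correlation). Ifit3, an interferon-induced antiviral gene, rose 25.3-fold, from 7.43 ± 0.03 in control to 12.09 ± 0.23 in starved cells (log2 fold change 4.66, SE 0.11, adjusted p = 4.71e-09). Msmo1, a sterol oxidase of the cholesterol pathway, fell 17.7-fold, from 11.33 ± 0.04 to 7.19 ± 0.09 (log2 fold change −4.14, SE 0.07, adjusted p = 7.67e-10). In all, limma with Benjamini-Hochberg adjustment called 5463 of 12393 genes (44.1%), of which 2735 were higher and 2728 lower in starved cells. A change of at least 1 on the log2 scale was reached by 327 of the higher and 216 of the lower genes. The groups did not overlap for 54.1% of genes, where chance gives 10% for 3 arrays against 3.

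The balance between higher and lower genes depended on how the arrays were scaled. Higher genes made up 50.1% of calls in the values as deposited, 41.9% with each array centred on its own median (2428 higher, 3362 lower), 21.5% with each array centred on its hybridization spike-ins (1673 higher, 6102 lower) and 8.45% with centring on the poly-A spike-ins (860 higher, 9321 lower). The median of all genes was −0.048 as deposited and became −0.095, −0.235 and −0.474 under these centrings. Directions are therefore given relative to the whole of the measured genes, as the deposited values set it. Centring on the poly-A spike-ins subtracts 0.43 from every difference, and from every list median, so any rise smaller than this lies below 0 under it. The centrings on spike-ins were chosen after the spike-in values were seen. Each subtracts a single value per array, so its error is shared by all genes. The mean poly-A shift was itself uncertain (0.426, 95% CI 0.26 to 0.593). The fit treats this error as separate for each gene. Counts, calls and adjusted p under the spike-in centrings, here and below, therefore rest on a shared uncertain shift and are not separate evidence for each gene.

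Interferon-stimulated genes held the largest rises. All 23 measured members of the interferon response list rose, with a median of 1.93, and all 23 also did so when adjusted over the list alone (camera adjusted p = 3.81e-20; adjusted p = 0.0689 with an estimated correlation). With centring on the poly-A spike-ins 21 of the 23 rose and 0 fell, with a median of 1.51. The 10 largest rises past the threshold were Ifit3, Ifit1 (4.33), the GTPase Iigp1 (4.11), the deconjugating protease Usp18 (3.72), Oasl2 (3.69), the chemokine Cxcl10 (3.60), Rtp4 (3.55), the antiviral enzyme Rsad2 (3.20), the GTPase Irgm2 (3.11) and the guanylate-binding protein Gbp3 (3.08). Their adjusted p lay between 4.71e-09 for Ifit3 and 2.22e-06 for Rsad2. Of 14 measured macrophage and blood cell markers 0 rose, 2 fell, Cd14 (−0.46) and Coro1a (−0.24), and 12 did not pass, and when adjusted over the list alone 1 fell.

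Genes of cholesterol synthesis fell. All 19 measured members of the cholesterol synthesis and uptake list fell, by a median of −1.92, and all 19 also when adjusted over the list alone (camera adjusted p = 9.32e-18). Among the 10 largest falls were Msmo1, the isoprenoid enzyme Idi1 (−3.76, SE 0.07, adjusted p = 1.23e-09), squalene epoxidase Sqle (−3.58), farnesyl diphosphate synthase Fdps (−2.57) and lanosterol synthase Lss (−2.51). The other large falls were Inmt, an amine N-methyltransferase, at −5.70 (from 10.31 ± 0.11 to 4.61 ± 0.15, near the dim end of the arrays), the cystathionine-cleaving enzyme Cth at −3.14, the growth factor binding protein Igfbp5 at −2.53, the transferrin receptor Tfrc at −2.51 and the pseudokinase Trib3 at −2.44. In the fatty acid synthesis and desaturation list 11 of 17 members fell, 1 rose and 5 did not pass, with a median of −0.62 (camera adjusted p = 4.59e-05; adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone, 13 fell and 1 rose. The elongase Elovl6 fell by 2.20 and fatty acid synthase Fasn by 1.32, while the phosphatidate phosphatase Lpin1 rose by 0.63 (adjusted p = 0.000358), a call lost with centring on the poly-A spike-ins (0.20). In fatty acid oxidation and lipolysis 7 of 23 members rose, 2 fell and 14 did not pass, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.228). The kinase Pdk4 (1.59) and the lipase Pnpla2 (1.26), named after their values were seen, were its highest members.

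ATF4 and integrated stress response targets fell, although single members went the other way. Of 26 measured targets 17 fell, 2 rose and 7 did not pass, with a median of −0.60 and the same counts when adjusted over the list alone (camera adjusted p = 5.62e-06; adjusted p = 0.154 with an estimated correlation). Cth and Trib3 fell most, and Ddit3, a transcription factor of the stress response, fell by 0.66 and Ddit4, an inhibitor of mTORC1 signalling, by 1.31. The stress protein Nupr1 rose by 0.70 and Gadd45a by 0.39, though Gadd45a lay at −0.039 with centring on the poly-A spike-ins. Asparagine synthetase Asns did not pass (11.78 ± 0.03 and 11.69 ± 0.09, difference −0.09, SE 0.07, adjusted p = 0.342), though it fell with centring on either spike-in set (−0.28 and −0.52). Of 13 amino acid transporters 10 fell and 3 did not pass, also when adjusted over the list alone, with a median of −0.46 (camera adjusted p = 0.00118; adjusted p = 0.2 with an estimated correlation). Slc1a4 fell by 1.34 and Slc38a4 by 1.16. Of 16 cytosolic aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, 12 fell, 1 rose and 3 did not pass, with a median of −0.37 (camera adjusted p = 0.000745; adjusted p = 0.274 with an estimated correlation), and adjusted over the list alone 12 fell and 2 rose. Wars fell 2.30-fold and Iars 2.26-fold, while Vars rose by 0.62, a call lost with centring on the poly-A spike-ins (0.20).

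Chaperones of the endoplasmic reticulum fell as well. Of 26 members of the list of ER chaperones and the unfolded protein response 19 fell, 2 rose and 5 did not pass, also when adjusted over the list alone, with a median of −0.38 (camera adjusted p = 2.18e-05; adjusted p = 0.0689 with an estimated correlation). Sdf2l1 fell by 1.94 (SE 0.09, adjusted p = 2.05e-07), and Hspa5, the main chaperone of this compartment, fell from 12.50 ± 0.05 to 11.26 ± 0.05 (adjusted p = 7.16e-07). Dnajb9 rose by 0.44 and Ero1b by 0.35, but of the dimmer probe sets of Ero1b 1 fell (−0.26) and another did not pass (0.075), the mean of its probe sets did not pass (0.055), and with centring on the poly-A spike-ins Dnajb9 lay at 0.017 and Ero1b at −0.080. In the heat shock list 9 of 17 members fell, 3 rose and 5 did not pass, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.269). Its risen members were Hspa4l (1.59), Hspb1 (0.74) and Dnajb1 (0.48).

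Genes for making ribosomes fell. Of 38 ribosome biogenesis genes 29 fell, 0 rose and 9 did not pass, also when adjusted over the list alone, with a median of −0.71 (camera adjusted p = 8.97e-11; adjusted p = 0.0689 with an estimated correlation). Rrs1, a ribosome assembly factor, fell by 1.74 and the nucleolar protein Nolc1 by 1.38. Of 40 cytosolic ribosomal protein genes 3 fell, Rpl12 (−1.31), Rps6 (−0.25) and Rps25 (−0.23), 0 rose and 37 did not pass (1 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.717). The probe sets of 31 of the 40 lay above 13 in control arrays, against highest values of 14.52 or more on the arrays, and the 3 that fell were dimmer (7.23, 9.61 and 8.71), so these values do not show that ribosomal protein transcripts were stable. With centring on the poly-A spike-ins 39 of the 40 fell, by a median of −0.44. The growth-promoting transcription factor Myc fell by 0.83 (adjusted p = 9.49e-06).

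Glycolytic genes and other targets of the hypoxia factor HIF fell in 18 of 23 cases, with 2 that rose and 3 that did not pass and a median of −0.89 (camera adjusted p = 6.36e-08; adjusted p = 0.0959 with an estimated correlation). Adjusted over the list alone, 19 fell and 2 rose. Hexokinase Hk2 fell 3.27-fold (8.88 ± 0.05 to 7.17 ± 0.05) and the glucose transporter Slc2a1 2.34-fold, while the histone demethylase Kdm3a rose by 0.66 and Ndrg1 by 0.36, with Ndrg1 at −0.068 under centring on the poly-A spike-ins. Of 52 oxidative phosphorylation genes 25 fell, 1 rose and 26 did not pass (26 fell and 1 rose adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.000421; adjusted p = 0.522 with an estimated correlation). Cytochrome c, Cycs, fell by 0.86 and the complex I subunit Ndufc1 by 0.69, and Ndufs4 was the member that rose (0.27, but −0.16 under centring on the poly-A spike-ins). Under that centring 50 of the 52 fell and 0 rose, with a median of −0.61. Of 31 proteasome subunits 11 fell, 4 rose and 16 did not pass, also when adjusted over the list alone, with a median of −0.16 (camera adjusted p = 0.043; adjusted p = 0.46 with an estimated correlation). Psmb5 fell by 0.51 and Psmb3 by 0.47. Psmd4 (0.31), Psmd8 (0.25), Psmc1 (0.23) and Psmc6 (0.20) rose, with Psmd4 at −0.12 and Psmd8 at −0.18 under centring on the poly-A spike-ins, where 0 subunits rose and 27 fell, and Psmd4 lost its call with the mean of its probe sets (0.12). The call of this list was lost without control replicate 1 (adjusted p = 0.083), without control replicate 3 (adjusted p = 0.0646) and in 2 other settings. Of 18 NRF2 targets, genes of antioxidant defence, 10 fell, 2 rose and 6 did not pass, also when adjusted over the list alone, with a median of −0.24 (camera adjusted p = 0.0459; adjusted p = 0.46 with an estimated correlation). Gsta4 fell by 0.77 and the cystine transporter Slc7a11 by 0.71, while Abcc1 rose by 0.32 and Osgin1 by 0.24, with Abcc1 at −0.11 and Osgin1 at −0.19 under centring on the poly-A spike-ins. The call of the NRF2 list was lost without control replicate 1 (adjusted p = 0.083), without starved replicate 3 (adjusted p = 0.0599) and in 4 other settings. Among the small rises named here and with the chaperones, those of Ero1b, Ndufs4, Osgin1 and Psmd8 each lost their call when certain single arrays were left out.

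**Figure D1:**
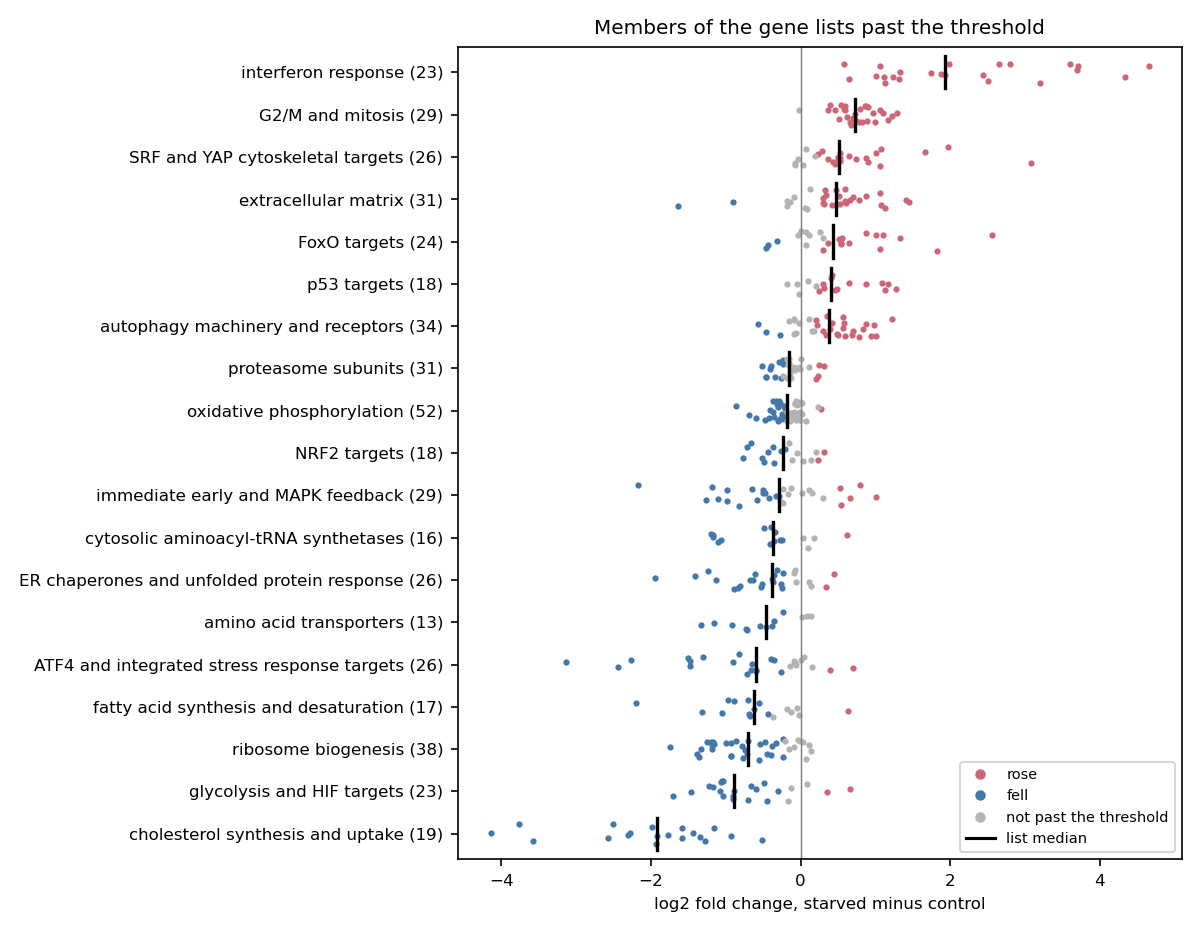
Log2 fold change (starved minus control, horizontal axis) of each measured member of the 19 gene lists past the threshold, with 1 point per gene, colour for rose, fell or not past the threshold, the list median as a bar and the number of members in brackets. All 23 interferon genes lie above 0 and all 19 cholesterol genes below 0, whereas with centring on the poly-A spike-ins the medians of the autophagy list (−0.052) and the p53 list (−0.016) turn below 0 and those of FoxO targets (0.008), matrix (0.046) and SRF and YAP targets (0.086) lie close to 0.

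Genes of late cell cycle stages rose. Of 29 genes of G2/M and mitosis 28 rose, also when adjusted over the list alone, and Tpx2 (−0.02) did not pass, with a median of 0.73 (camera adjusted p = 3.65e-15; adjusted p = 0.0651 with an estimated correlation). The spindle protein Nusap1 rose by 1.29 and the kinetochore protein Cenpf by 1.10. With centring on the poly-A spike-ins 19 of the 29 rose and 1 fell, with a median of 0.31. In the deposited scaling DNA replication and G1/S genes went both ways, with 12 of 32 that rose, 14 that fell and 6 that did not pass (13 and 14 adjusted over the list alone), and the list was not called (camera adjusted p = 0.862). After centring on the poly-A spike-ins 2 of them rose and 18 fell. Cyclin D1, Ccnd1, which drives entry into the cycle, fell from 10.57 ± 0.02 to 9.33 ± 0.03 (adjusted p = 5.76e-07). Ccne2 (−1.75) and Ccne1 (−1.45) fell further, while the helicase subunits Mcm7 (0.69) and Mcm6 (0.68) rose. These 4 genes were named after their values were seen. Of 18 p53 targets 13 rose and 5 did not pass (13 rose and 1 fell adjusted over the list alone), with a median of 0.41 that became −0.016 with centring on the poly-A spike-ins, where 5 rose and 4 fell (camera adjusted p = 2.01e-05; adjusted p = 0.0689 with an estimated correlation). The death-promoting genes Pmaip1 and Perp rose by 1.27 and 1.12.

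Cytoskeletal genes rose. Of 26 cytoskeletal targets of SRF and YAP 20 rose and 6 did not pass (21 rose adjusted over the list alone), with a median of 0.51 (camera adjusted p = 8.01e-09; adjusted p = 0.0689 with an estimated correlation). With centring on the poly-A spike-ins 10 rose and 5 fell, with a median of 0.086. The smooth muscle actin Actg2 rose 8.45-fold, from 5.84 ± 0.21 to 8.92 ± 0.12, and the actin-binding protein Tagln 3.94-fold, whereas beta-actin, Actb, did not pass (−0.07, SE 0.09, adjusted p = 0.534) and lay lower with centring on either spike-in set (−0.26 and −0.50). Of 31 extracellular matrix genes 22 rose, 2 fell and 7 did not pass, also when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 6.35e-06; adjusted p = 0.355 with an estimated correlation). The matrix glycoproteins Tnc and Postn rose by 1.44 and 1.41, and the members that fell were the matrix-degrading proteases Mmp3 (−1.64) and Mmp13 (−0.91). With centring on the poly-A spike-ins 9 matrix genes rose and 9 fell. In the list of immediate early genes and MAPK feedback 15 of 29 members fell, 5 rose and 9 did not pass (18 fell and 5 rose adjusted over the list alone), with a median of −0.29 (camera adjusted p = 0.0103; adjusted p = 0.428 with an estimated correlation). The receptor-signalling inhibitor Spry1 fell by 2.17, Phlda1 by 1.26 and Fos by 0.33. The risen members were Klf10 (1.01), Fosl2 (0.79), Edn1 (0.67), Egr1 (0.54) and Junb (0.53). This list lost its call with centring on the poly-A (adjusted p = 0.14) or the hybridization spike-ins (adjusted p = 0.0647).

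Autophagy genes rose in the deposited scaling, whereas lysosomal genes went both ways in it. Of 34 genes of the autophagy machinery and receptors 22 rose, 3 fell and 9 did not pass, also when adjusted over the list alone, with a median of 0.37 that became −0.052 with centring on the poly-A spike-ins, where 9 rose and 12 fell (camera adjusted p = 4.59e-05; adjusted p = 0.2 with an estimated correlation). Rb1cc1, a scaffold of the kinase complex that starts autophagy, rose by 1.23, its kinase Ulk1 by 1.00, the phosphoinositide-binding protein Wipi1 by 0.94 and the cargo receptor Sqstm1 by 0.99. Of the dimmer probe sets of Wipi1 1 also rose (1.38), while the others did not pass (−0.025, −0.165 and −0.258). The members of the list that fell were Atg3 (−0.56), Bnip3 (−0.46) and Atg4b (−0.28). Map1lc3b, which encodes the autophagosome protein LC3B, did not pass on its brightest probe set (0.16, adjusted p = 0.156), while 2 dimmer probe sets rose (0.69 and 0.61) and the mean of its probe sets rose by 0.40. The brightest probe set passed as lower with centring on the poly-A spike-ins (−0.27, adjusted p = 0.0355), a call that rests on the uncertain shift shared by all genes. Of 48 lysosomal genes 10 rose, 15 fell and 23 did not pass, also when adjusted over the list alone, and the list was not called (median −0.085, camera adjusted p = 0.569). With centring on the poly-A spike-ins 2 rose and 38 fell, with a median of −0.51. Its lowest and highest members, named after their values were seen, were Gusb (−1.33) and the cholesterol exporter Npc1 (0.90). Of 16 vacuolar ATPase subunits, which acidify lysosomes, 5 fell, Atp6v1b2 (0.42) rose and 10 did not pass, also when adjusted over the list alone, without a call (camera adjusted p = 0.569). Those that fell were Atp6v1h (−0.65), Atp6v0a2 (−0.41), Atp6v0e (−0.36), Atp6v0b (−0.31) and Atp6v0e2 (−0.23), and with centring on the poly-A spike-ins 15 fell and 0 rose. Tfeb, a transcription factor of lysosomal and autophagy genes, did not pass (6.99 ± 0.12 and 7.15 ± 0.12, difference 0.17, adjusted p = 0.159). Tfeb passed as lower with centring on the poly-A spike-ins (−0.26, adjusted p = 0.0251), a call that rests on the same shared shift. The lysosomal channel gene Mcoln1 rose by 0.33 (adjusted p = 0.00575), but its call was lost without probe sets that can bind several transcripts (0.18) and it lay at −0.098 with centring on the poly-A spike-ins.

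Of 24 FoxO targets 14 rose, 3 fell and 7 did not pass (16 rose and 3 fell adjusted over the list alone), with a median of 0.44 that was 0.008 with centring on the poly-A spike-ins, where 7 rose and 8 fell (camera adjusted p = 4.99e-05; adjusted p = 0.111 with an estimated correlation). Txnip, an inhibitor of glucose uptake, rose 5.87-fold, from 9.54 ± 0.15 to 12.10 ± 0.03, and the ubiquitin ligase gene Fbxo32 rose 3.53-fold. Bnip3 (−0.46), Klf15 (−0.43) and Sod2 (−0.31) fell. In the deposited scaling members of the mTORC1 and nutrient sensing list went both ways, with 8 of 25 that rose, 7 that fell and 10 that did not pass (8 and 8 adjusted over the list alone), without a call (camera adjusted p = 0.818). In this list 2 rose and 17 fell with centring on the poly-A spike-ins, and 5 rose and 12 fell with the hybridization spike-ins. In the circadian clock list 6 of 15 members rose, 4 fell and 5 did not pass (6 and 5 adjusted over the list alone), without a call (camera adjusted p = 0.862). The repressors Nr1d2 (1.44) and Nr1d1 (1.30) were its highest members, and Cry1 (−1.33), Arntl (−1.14), Bhlhe40 (−1.02) and Hlf (−0.91) were those that fell. Of 23 NF-kappaB and chemokine genes 9 rose, 8 fell and 6 did not pass (10 and 8 adjusted over the list alone), without a call (camera adjusted p = 0.647). The subunits Relb (2.08) and Nfkb2 (1.82) rose most and the chemokine Cxcl5 (−1.37) fell most. Of 13 glucocorticoid receptor targets 4 rose, Mt2 (1.08), Mt1 (0.88), Glul (0.77) and Nfkbia (0.35), and 5 fell, Errfi1 (−1.31), Cebpd (−1.18), Dusp1 (−0.48), Zbtb16 (−0.40) and Fkbp5 (−0.39), also when adjusted over the list alone, without a call (camera adjusted p = 0.682). With centring on the poly-A spike-ins the medians of 5 lists without a call turned from above to below 0, namely fatty acid oxidation (−0.39), DNA replication (−0.35), mTORC1 (−0.42), NF-kappaB (−0.27) and fibroblast markers (−0.36). Under it 2 genes rose and 16 fell in fatty acid oxidation, 2 and 14 in heat shock, 4 and 9 in the circadian clock, 5 and 12 in NF-kappaB and 3 and 9 in glucocorticoid targets.

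Camera called none of the lists of cell type markers, while fry called endothelial (adjusted p = 0.0263) and adipocyte markers (adjusted p = 0.0128) as lower. Of 14 fibroblast markers 6 rose, 4 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.717), with Col1a1 at 0.47 and Twist2 at −1.15. Endothelial markers had 0 of 11 that rose and 4 that fell, Flt1 (−0.47), Ramp2 (−0.38), Pecam1 (−0.27) and Kdr (−0.27), or 3 adjusted over the list alone (camera adjusted p = 0.519). Of 8 adipocyte markers 0 rose and 2 fell, Fabp4 (−0.81) and Cebpa (−0.79), also when adjusted over the list alone (camera adjusted p = 0.179). Cdh1 (0.91) was the only epithelial marker of 12 to pass, also when adjusted over the list alone (camera adjusted p = 0.717). Of 12 skeletal muscle markers Acta1 (1.37) and Tnnt2 (0.46) rose and Ckm (−0.30) fell, also when adjusted over the list alone (camera adjusted p = 0.862), and of 13 neural markers Map2 (0.53) and Mbp (0.49) rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.818). The macrophage list, given with the interferon genes, had a camera adjusted p of 0.417. These counts hold for the deposited scaling. Most markers of every cell type fell with centring on the poly-A spike-ins, with 0 that rose and 9 that fell for fibroblast, 0 and 10 for endothelial, 0 and 8 for adipocyte, 1 and 11 for epithelial, 1 and 10 for skeletal muscle, 0 and 11 for neural and 0 and 14 for macrophage markers.

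**Figure D2:**
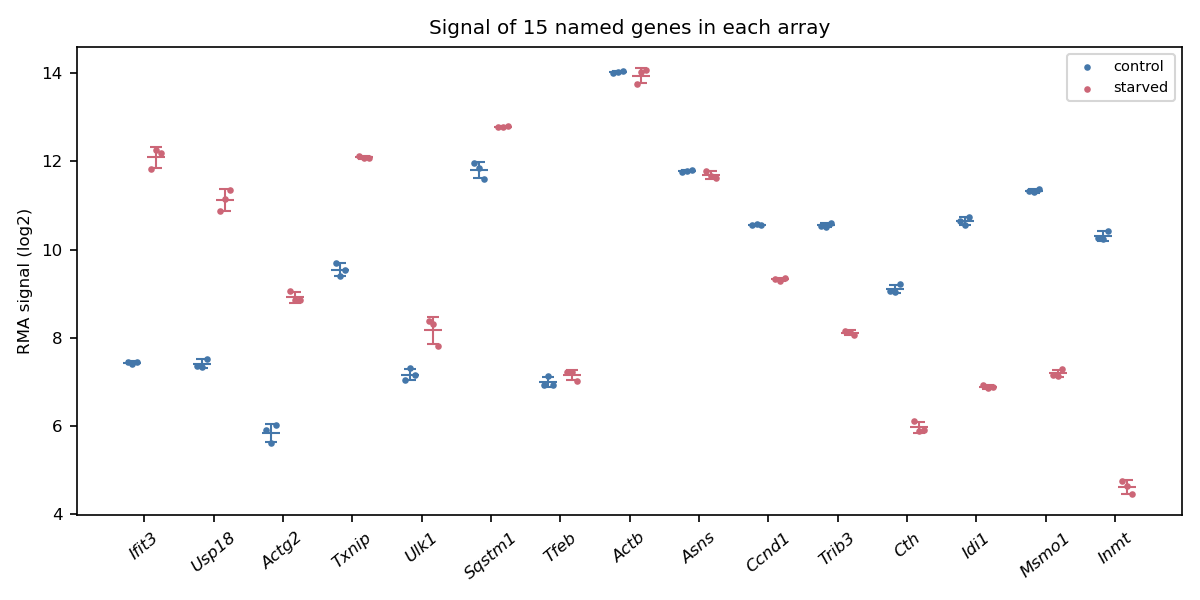
Log2 array signal (vertical axis) of 15 named genes in each of the 3 control and 3 starved arrays, with points for arrays, a long bar for the group mean and error bars for the SD. The control and starved arrays lie apart for Ifit3 (7.43 and 12.09 on average) and Msmo1 (11.33 and 7.19), while they overlap or lie close for Tfeb, Actb and Asns. Actb and Asns lie lower in starved arrays under centring on either spike-in set, and Tfeb (−0.26) with the poly-A spike-ins.

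Camera, which sets a list against all other genes with a preset correlation of 0.01, called 19 of 36 lists, 7 up and 12 down. With a correlation estimated per list, the call of cholesterol synthesis and uptake held (adjusted p = 0.0228) and the other 18 did not. This setting also bases its test on the number of arrays instead of genes, so a lost call need not mean correlated genes. The estimated correlation of the ER chaperone list (−0.0214) lay below the preset, yet its unadjusted camera p rose from 6.07e-06 to 0.00718. The estimated correlations of the interferon (0.232), oxidative phosphorylation (0.245) and matrix lists (0.282) lay above it. Fry's directional test, which asks whether a list's genes move on balance one way without setting them against other genes, called 26 lists, including all 19 in the same direction. Its additional calls were fatty acid oxidation, DNA replication, ribosomal proteins, heat shock, glucocorticoid targets, endothelial and adipocyte markers. For DNA replication fry's direction was down (adjusted p = 0.0492) while camera's was up without a call. Median, mean and camera direction differed in sign for the lists of DNA replication (median 0.077, mean −0.068), the circadian clock (−0.083, 0.063), fibroblast (0.07, −0.029), skeletal muscle (−0.088, 0.05) and neural markers (−0.06, 0.034).

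The 6 arrays behind every gene group above also held signals of RNA quality and of spike-ins. The 3′ minus 5′ signal of beta-actin was 0.017 ± 0.009 in control and 0.108 ± 0.042 in starved arrays (difference 0.091, 95% CI 0.022 to 0.16; exact two-sided permutation p = 0.1, the smallest possible for 3 against 3), and that of Gapdh differed by −0.023 (exact permutation p = 0.8). Poly-A spike-in signals lay 0.43 higher and hybridization spike-in signals 0.19 higher in starved arrays (exact permutation p = 0.1 each).

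**Figure D3:**
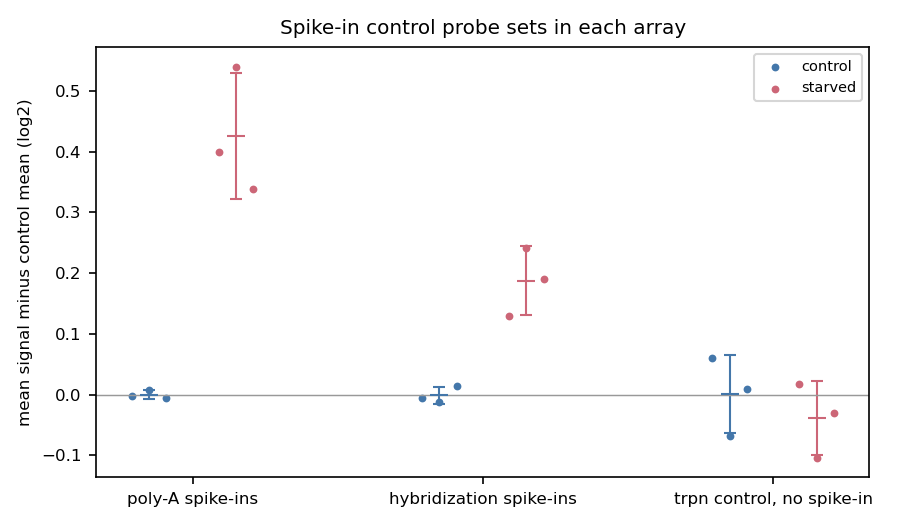
Mean log2 signal of the poly-A spike-in, hybridization spike-in and trpn control probe sets in each array, minus the control mean (vertical axis), with points for arrays, a long bar for the group mean and error bars for the SD (n = 3). All 3 starved arrays lie above all 3 control arrays for both spike-in sets (0.43 and 0.19 on average), and the groups overlap for trpn (−0.039).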

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

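Both tests of the spike-in pattern were chosen after the result was seen. Control probe sets outside the gene comparison held signals above the control arrays. Probe sets of the poly-A spike-ins, bacterial transcripts meant to be added to the RNA before labelling, were 0.426 higher on the log2 scale in starved arrays (95% CI 0.260 to 0.593), with 24 of 24 probe sets higher on average. Those of the hybridization spike-ins, meant to be added to the labelled mix, were 0.188 higher (95% CI 0.094 to 0.281), with 18 of 18 probe sets higher. The trpn probe sets, which match no spike-in, differed by −0.039. The exact permutation p was 0.1 for each spike-in set, the smallest possible for 3 arrays against 3, and 0.5 for trpn.

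The poly-A set lay a further 0.239 higher than the hybridization set (95% CI 0.106 to 0.372). A shift at the hybridization step alone was predicted to lift both sets by the same amount. The sets lay at different levels in control arrays, 7.42 for poly-A and 10.13 for hybridization spike-ins. Whether a shift has the same log2 size at both levels after RMA was not tested, so the gap does not decide on the hybridization step. Less messenger RNA per unit of total RNA in starved cells stays open as a candidate explanation, since in 3 of 3 starved arrays the poly-A signal relative to the hybridization signal lay above every control array. Unequal amounts of added spike-ins or unequal labelling were not tested, because the labels do not state that or how spike-ins were added, so they cannot be told apart from it.

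The B1 repeat probe set was 0.487 higher and the B2 repeat probe set 0.134 higher in starved arrays (exact permutation p = 0.1 each). Probe sets left out of the gene comparison also passed the threshold, with 172 higher and 190 lower among the 1555 with no gene listed, and 83 higher and 116 lower among the 691 with several genes.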

How the results depend on the processing

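Centring on spike-ins was chosen after the results were seen, and the other settings were fixed before the data were examined. Of 84 named genes 68 kept direction and call under every alternative run on them. Most of these genes were named for large changes or small adjusted p in the same arrays, so this share does not speak for all calls. Of the 5463 calls, 3588 kept direction and call with centring on the poly-A spike-ins. The 5463 calls (2735 higher, 2728 lower) became 8339 (4156 and 4183) with each probe set tested on its own, 543 (327 and 216) with a change of at least 1, 2253 (1314 and 939) with treat, 10181 (860 and 9321) with centring on the poly-A spike-ins and 1673 higher and 6102 lower with the hybridization spike-ins; at an adjusted p below 0.01 there were 2149 higher and 1782 lower genes (54.7% higher). More or stricter tests account for the first 3 and the last, and the centrings shift every gene alike by construction. The error of that shift is shared by all genes, so calls gained or lost under the centrings are not separate evidence for each gene. Without 1 array in turn the calls ranged from 4541 to 5317 (higher 2355 to 2753, lower 2186 to 2735), the called lists from 17 to 19, the 3′ minus 5′ difference of beta-actin from 0.076 to 0.115 and that of Gapdh from −0.045 to 0.014. With an estimated correlation 1 list was called instead of 19. Fewer than 19 lists were called elsewhere only because 3 lists near the threshold lost their call, all of them in the same direction. These were NRF2 targets (camera adjusted p from 0.02 to 0.083 over the 17 alternatives other than fry and the estimated correlation; lost without control replicate 1 at 0.083, without starved replicate 3 at 0.0599, with median centring, with the block and with both spike-in centrings), proteasome subunits (0.0158 to 0.083; lost without control replicate 1 at 0.083, without control replicate 3 at 0.0646, without shared probe sets and with poly-A centring) and immediate early genes (0.00132 to 0.14; lost with both spike-in centrings). Poly-A centring reversed 11 named genes, namely Abcc1 (−0.109), Ero1b (−0.080), Gadd45a (−0.039), Mcoln1 (−0.098), Ndrg1 (−0.068), Ndufs4 (−0.156), Osgin1 (−0.191), Psmd4 (−0.116), Psmd8 (−0.179), Tfeb (−0.26) and Map1lc3b (−0.27), since it subtracts 0.426 from every difference and their differences were smaller; the last 2 had no call before and passed as lower. Of these, 4 lost their call without a single array: Osgin1 without any array but starved replicate 3 (0.19 to 0.25), Psmd8 without any control array or starved replicate 1 (0.19 to 0.25), Ndufs4 without any control array (0.26 to 0.28) and Ero1b without control replicate 2 (0.30), control replicate 3 (0.32) or starved replicate 2 (0.22). With the mean of a gene's probe sets Ero1b (0.055) and Psmd4 (0.124) lost their call. Map1lc3b gained a call without starved replicate 2 (0.23) and with the mean of its probe sets (0.40), both as higher. Fry called the DNA replication list as lower, against camera's direction, with the same list median (0.077). Deviations of same-numbered arrays correlated at −0.0046, −0.022 and 0.0021, so no shared effect of the replicate number was seen. These values do not show whether arrays shared a culture or day, which the labels do not state. With the replicate block 5274 genes (2669 higher, 2605 lower) and 18 lists were called, and no named gene changed its call. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes and 1 as many lists, the real split itself in both cases. The other splits called 0 genes each, but between 7 and 16 lists, so camera with the preset correlation called lists where no gene passed. These splits still divided the starved arrays unequally, so part of the starved difference remained and the list counts are not a rate of false calls. The 10 splits are too few for a share below 0.05. Dim genes such as Ifnb1 lie close to the floor of the arrays, which limits their folds.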

Other observations

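The lists of splicing factors, Id genes and interferon-inducible GTPases, the blood cell and scaling tests and the final decision on interferon beta were chosen after the values were seen, while the shared probe sets, sex and mTORC1 tests were set before. SR proteins, which bind pre-mRNA and guide splicing, were mostly lower in starved fibroblasts. Of 11 measured SR splicing factors 9 fell and 2 rose, Srsf11 (0.53) and Srsf4 (0.22, below 0 with centring on the poly-A spike-ins), with a median of −0.48. Srsf2 fell from 11.08 ± 0.02 to 9.09 ± 0.14 (−1.99), Srsf3 by 1.61 and Srsf6 by 1.37. The list was written after 3 of its members had been seen, so these counts describe it and test nothing.

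Id genes, inhibitors of differentiation induced by bone morphogenetic proteins, and the inhibitory Smads were lower too. The list also holds Bambi and Smad9, which are not inhibitory Smads. Of its 8 members 7 fell and Smad9 did not pass, with a median of −0.52. Id2 fell by 2.27 (9.22 ± 0.05 to 6.95 ± 0.05), Id1 by 2.11 and Id3 by 1.07. As the Id list was written after 2 of its members had been seen, this too is a description. Among 10 interferon-inducible GTPases, which act on membranes around pathogens, Gbp7 rose by 2.94 and Igtp by 2.47. All 10 rose, but 9 had been seen before the list was written, so this count describes them and tests nothing. Xist, the RNA that silences an X chromosome in female cells, rose from 11.77 ± 0.09 to 12.73 ± 0.01 (0.96, adjusted p = 4.36e-06). Xist was thus bright in both groups, which argues against female cells in 1 group and male cells in the other. The 3 measured Y-linked genes differed by at most 0.099 and lay near the floor of the arrays in both groups (2.77 to 3.30). The Xist difference of 0.957 lay under the bound of 1 set beforehand, while its 95% CI (0.798 to 1.117) reached above it. A requirement on the interval was not part of that bound. Unequal shares of female and male cells in the groups were not tested.

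The rise of the interferon genes has candidate explanations that the tables partly exclude. Blood cells or macrophages in the starved cultures would bring their own transcripts, but the median of their 14 markers was −0.134, the brightest of them, Cd14, fell from 7.75 to 7.29, Lyz2 was at 4.95 and 5.12, and fibroblasts held 1 of the 14 above the array median. Probe sets shared between related transcripts are argued against by the list without them, where 22 of 22 members rose with a median of 1.956. An increased interferon beta transcript stays open, since Ifnb1 was 0.373 higher (95% CI 0.208 to 0.537, 3.97 ± 0.09 to 4.34 ± 0.04, adjusted p = 0.0023) but lay near the floor of the arrays, at −0.054 with centring on the poly-A spike-ins and 0.185 with the hybridization spike-ins, and the requirement that its rise hold under both was added after these values were seen. The interferon gamma gene Ifng did not pass (0.257, adjusted p = 0.0577) and lay near the floor as well. Its receptor genes Ifngr1 (0.438) and Ifngr2 (0.32, below 0 with centring on the poly-A spike-ins) rose. The interferon beta receptor genes Ifnar1 (−0.132) and Ifnar2 (−0.036) did not pass. Interferon gamma was not tested as an explanation. Starvation itself, which the design names, also stays open, since no sample separates it from a response to anything else that differed between the cultures.

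The lists of cholesterol synthesis, ATF4 targets, glycolysis and ribosome biogenesis were lower together, and lower output of mTORC1, a kinase complex that promotes all of them in fed cells, is a candidate explanation. A scaling shift of all genes alike would leave the gap between a list and the other genes of an array unchanged. The gap nearest to 0, that of ATF4 targets, was −0.545 in starved minus control arrays (95% CI −0.589 to −0.500). Camera had already called these lists lower than the other genes in the same arrays, so a gap below 0 was given in advance. The gaps therefore describe the lists and test nothing. Scaling that depends on the signal level was not tested. As a test on genes outside the fixed lists, purine and pyrimidine synthesis genes had 9 of 16 members that fell and 4 that rose (Ctps2, Paics, Ctps and Adss), with a median of −0.37 (camera adjusted p = 0.0254; adjusted p = 0.151 with an estimated correlation). In the pentose phosphate pathway 2 of 7 fell, Rpia (−1.08) and Rpe (−0.31), with a median of −0.17 that did not pass (camera adjusted p = 0.0848; adjusted p = 0.151 with an estimated correlation). As the prediction asked for both lists, the hypothesis stays open.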
